A study of Lacticaseibacillus rhamnosus with 9 samples.

How the data were processed

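RNA was sequenced from 9 cultures of the bacterium Lacticaseibacillus rhamnosus Lcr35: 3 of Lcr35 alone, 3 of Lcr35 with sodium thiosulfate (STS, 1 g/L in the medium) and 3 of Lcr35 with the yeast Candida albicans. Per the labels' protocols, Lcr35 grew for 48 h in MRS, a rich medium for lactobacilli, with or without STS, the yeast grew in Sabouraud dextrose broth, and co-cultures combined both in equal parts for 6 h at 37 °C. Every co-culture therefore also held Sabouraud medium, so the yeast and its medium are confounded. The protocols do not say whether the other cultures were diluted or kept for another 6 h in the same way. RNA was isolated after mechanical lysis, treated with DNase and depleted of ribosomal RNA, and libraries were made with a stranded kit and sequenced as single reads, per the labels' protocols. The labels do not say whether replicates came from separate starting cultures, so the p-values measure only the spread between these samples, which may be technical.

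The deposited count table holds whole-number read counts per gene as the authors made them, with no normalization. Per the submitters' processing notes, the tools named are bcl2fastq 2.20, FastQC 0.11.9, MultiQC 1.11, BWA 0.7.15-r1140, featureCounts 2.0.3, R 4.1.1 and DESeq2 1.32.0. The genome build, the annotation and the strand setting of the counting are not given in the sources used here. Genes on opposite strands that overlap may therefore share counts, and genes with numbered symbols (such as clpC_1 and clpC_2) can be close copies whose reads the counting may have split. The other deposited table holds normalized signal, which is each count divided by 1 size factor per sample. This was checked: the ratio of the deposited tables was constant within each sample, with a largest relative deviation of 5.00e-15. Both tables list 2781 genes, of which 1631 carry a gene symbol and 1150 only an identifier. 16 genes had no count in any sample, and 0 sample columns were left unused. The tables pair identifiers with symbols and give no coordinates or product descriptions. The identifiers were compared with a table of RefSeq genes of L. rhamnosus GG, and 0 matched, so that table was not used. Symbols are the authors'; some are names of eukaryotic genes, as annotation by similarity gives, and what a gene is known to do is background from its symbol.

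Genes were tested with edgeR 4.0.16 (R 4.3.3, limma 3.58.1) by its quasi-likelihood F test on the counts, with TMM scaling factors, robust dispersion and the filterByExpr filter. The filter left 2732 genes and removed 49. All 9 samples entered a single fit with a mean per group, and 3 contrasts were tested: STS against Lcr35 alone, Candida against Lcr35 alone, and Candida against STS. P-values were adjusted by Benjamini-Hochberg over the genes tested, and genes with an adjusted p under 0.05 are called changed, with at least a 2-fold change counted beside. Standard errors (SE) come from the F statistic. CPM values are counts scaled to the TMM-adjusted library sizes, given as mean ± SD over 3 libraries. The median SE of a log2 fold change was 0.20 for STS and 0.22 for Candida. Depth limited genes with few counts: 3 counts in a library of Lcr35 with Candida correspond to 0.101 to 0.138 CPM of the total count. For a gene with no count in a group, a bound was computed against a floor of 3 counts over the group, and for 1 to 3 counts a ratio with a 95% exact binomial interval. Both cover counting error only, since reads without molecular identifiers are not independent molecules.

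25 gene lists were fixed by symbol before the data were examined. 20 held at least 4 tested genes and were tested with camera, which asks whether a list moved relative to all other genes, with a preset correlation between genes of 0.01. fry, which asks whether a list's genes move on balance in 1 direction, and camera with an estimated correlation were alternatives. The lists of phage genes and transposases, defined by product text only, matched 0 genes, since no product text was at hand. The list of C. albicans genes held symbols, of which 0 matched. The list of peptidoglycan hydrolases, chitin-related enzymes and bacteriocins held fewer than 4 genes, and that of stable RNAs held 1 gene (ssrA), so neither was tested. In the phosphotransferase list, the symbols gatA, gatB and gatC also name subunits of a tRNA amidotransferase; leaving out gatA_1, gatB_1 and gatC_1, together with a wider match of symbols, changed no list call. Beside each count of members called over all genes tested, the count adjusted over the list alone is given where it differs.

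The rule for the genes named was fixed before the data were examined. For each comparison it took the 10 largest rises and the 10 largest falls among called genes with a symbol, a mean of at least 20 counts over the 6 samples, and no overlap between the groups' values. It also took up to 4 members with the smallest adjusted p from each list that passed and up to 2 from each other list. The rule gave more genes than the text names: the 10 largest rises and falls are named for STS and for Candida, and of the others only some, so several are not reported here. Genes named outside the rule are said to be chosen after their values were seen.

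Replicates were compared before they were averaged. Counts of the same group differed by 154 to 868 times the sampling noise (chi-square over its degrees of freedom), so the columns are separate measurements, and log2 CPM values correlated across genes with r between 0.975 and 0.994. Libraries of Lcr35 alone and of Lcr35 with STS correlated as closely (0.977 to 0.993). By the chi-square of counts, Lcr35 alone replicate 3 stood apart from the other controls (865 and 868 times the noise), further than Lcr35 alone replicate 2 from Lcr35 + STS replicate 2 (309). By the correlation of log2 CPM, Lcr35 alone replicates 2 and 3 were instead the closest controls (r = 0.991). Lcr35 alone replicate 1 correlated with them at 0.986 and 0.983. The titles number the replicates 1 to 3 in each group. Deviations from the group means correlated between same-numbered samples of Lcr35 alone and Lcr35 with STS (r = 0.40, 0.45 and 0.49 across genes), and between those of Lcr35 with STS and with Candida (0.25, 0.11 and 0.11). By the rule used here (every r over 0.1) these numbers pair the samples of these groups, on evidence from the data and not from a statement in the labels. For Lcr35 with STS and with Candida this evidence is weak, since differently numbered samples reached 0.089. Between Lcr35 alone and Lcr35 with Candida, differently numbered samples reached 0.16, so an r over 0.1 alone does not show pairing. A fit with the replicate number as a block is an alternative, and its values stand beside the results whose call it changes.

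The tests were checked on counts simulated from the means of Lcr35 alone, at each library's TMM-adjusted size and with the fitted dispersions. A known set of genes was changed (199 after filtering). For STS, edgeR recovered 20.9% of genes changed 1.5-fold, 77.3% of those changed 2-fold and 98.5% of those changed 4-fold among 2726 genes, and 10 of 140 calls were false. For Candida the shares were 17.9%, 68.7% and 95.5% among 2725 genes, with 10 of 131 calls false. For Candida against STS they were 26.9%, 77.6% and 100% among 2729 genes, with 10 of 146 calls false. The simulations changed far fewer genes than the 2198 of 2732 called in co-culture. They therefore do not cover the scaling of the co-culture libraries or the extent of their changes. In the check of camera, 1 list changed 1.5-fold passed in each comparison. Of 19 unchanged lists, 1 passed for STS, 0 for Candida and 0 for Candida against STS. Genes were drawn independently, so this check does not cover correlation between genes. For STS the estimated correlation was 0.37 in the heat shock, 0.47 in the ribosomal, 0.54 in the purine and 0.03 in the thiol redox list. The alternatives were other scalings (RLE, upper quartile), DESeq2 1.42.0, no filter, at least 50 counts in at least 3 samples, only the 6 samples of a comparison, the replicate block, each library left out in turn, the 10 genes with the highest mean share over all libraries and stable RNAs left out, limma on log2 of the deposited normalized values with a pseudocount of 1, and counts thinned to the smallest library total. Scaling by library totals alone, thinning to the smallest size factor, the block within 6 samples and a wider match of symbols were added after the data had been seen. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.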

Results

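The transcriptome of Lacticaseibacillus rhamnosus Lcr35, a lactic acid bacterium used as a probiotic, was measured by RNA-seq in 9 libraries. Lcr35 was grown alone (n = 3), with sodium thiosulfate (STS), a soluble inorganic sulfur source (n = 3), or together with Candida albicans SC5314, a commensal and opportunistic yeast (n = 3). The total count assigned to Lcr35 genes was 39518519 to 40357848 per library for Lcr35 alone, 32366314 to 34754613 with STS and 21730875 to 29815178 with Candida. The median count per gene was 2667 to 2882, 1979 to 2046 and 326 to 486 in these groups.

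Counts of the co-culture libraries lay in fewer genes. The 10 most abundant genes of each library took 23.3% ± 3.38 (SD, n = 3) of all counts in Lcr35 alone, 27.1% ± 1.68 with STS and 52.9% ± 3.22 with Candida. The most abundant gene in each group, gene_00632, which carries no symbol and was chosen after its values were seen, rose from 7.70% ± 2.15 of all counts in Lcr35 alone to 26.5% ± 4.34 in co-culture. Its log2 fold change was 3.67 on TMM-scaled library sizes (SE 0.30, adjusted p = 4.74e-07, edgeR), and 1.78 by library totals, the scale of these shares. The Clp chaperone gene clpC_2 (gene_02075) took 6.92% ± 0.966 of the co-culture counts (log2 fold change 4.28 against Lcr35 alone, SE 0.31, and 2.40 by library totals). The transfer-messenger RNA ssrA (gene_00252), which rescues stalled ribosomes, rose by 3.89 on the log2 scale (SE 0.18), and by 2.02 by library totals.

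**Figure D1:**
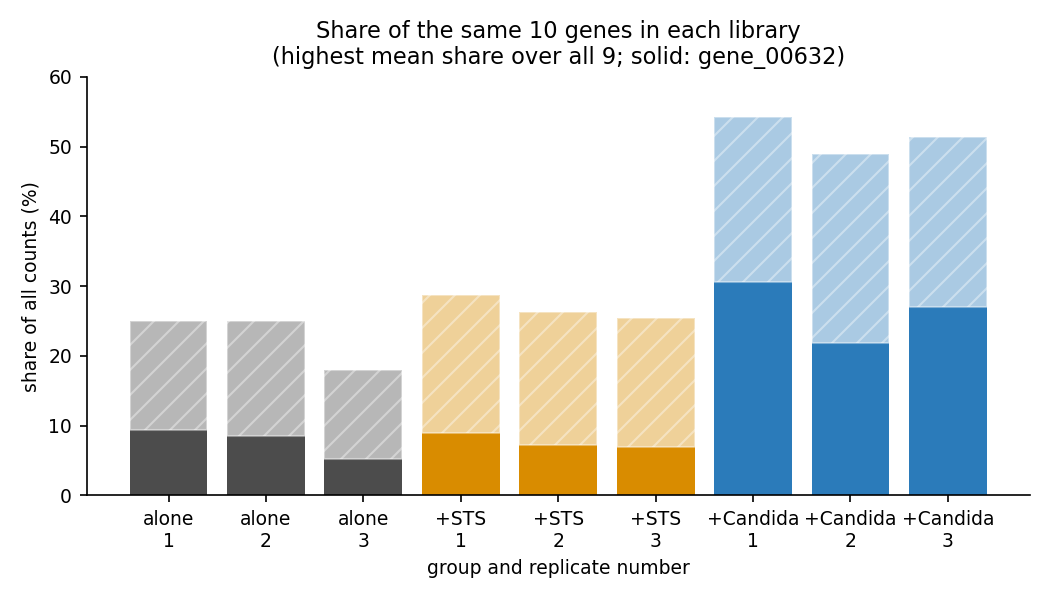
Share of all counts (y axis, %) taken by the same 10 genes, those with the highest mean share over all libraries, in each of the 9 libraries (x axis, group and replicate number). The solid part of each bar is gene_00632 and the hatched part the other 9 genes; the 3 co-culture libraries reach 48.9% to 54.3%, all above the 18.0% to 28.8% of the 6 others.

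The comparison of Lcr35 with STS against Lcr35 alone asks which genes respond to the sulfur source. With STS, transcripts of serS (gene_02215), the seryl-tRNA synthetase, rose from 905 ± 33.5 to 3297 ± 175 CPM (log2 fold change 1.86, SE 0.15, adjusted p = 0.000139). Transcripts of glmS (gene_00271), which makes glucosamine 6-phosphate for the cell wall, dropped from 833 ± 78.0 to 159 ± 18.3 CPM (log2 fold change -2.39, SE 0.24, adjusted p = 0.000766). The gene of the enzyme that breaks glucosamine 6-phosphate down, nagB (gene_01251), moved the other way, from 193 ± 10.6 to 411 ± 26.6 CPM (log2 fold change 1.09, SE 0.14). Genes of the dlt cluster, which attaches D-alanine to teichoic acids, fell: dltD (gene_00536) by 1.70, dltC (gene_00537) by 1.52 and dltA (gene_00539) by 1.70. The gene between them, patA (gene_00538), also fell by 1.75 on the log2 scale. Their level varied in the control group: dltD stood at 636, 624 and 1254 CPM in Lcr35 alone replicates 1, 2 and 3, and at 257 ± 23.9 CPM with STS, and without replicate 3 of Lcr35 alone its log2 fold change was -1.29.

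Further log2 rises with STS were 1.66 (SE 0.24) for fetA and 1.48 (SE 0.20) for fetB, named for an iron exporter, with neighbouring identifiers (gene_01547 and gene_01546), and 1.51 for each of glnQ_3 and yecS_2 (gene_02699 and gene_02700), named for amino acid uptake. The manganese transporter gene mntH_1 (gene_01704) decreased by 1.77 (SE 0.19), from 394 ± 92.1 to 116 ± 12.5 CPM, and the zinc uptake genes znuC and znuB (znuB chosen after its values were seen) rose by 0.99 and 0.95. Among genes with a symbol, the remaining large rises were GLO5_2 (1.72), nanT (1.70), hrcA (1.39), hisC_1 (1.38) and psaA (1.37). The remaining large falls among them were bceA_1 (-2.10), yxdM_1 (-2.02), mepH_2 (-1.61) and czrA_2 (-1.10). Genes without a symbol were outside the rule. Of these, chosen after their values were seen, gene_01380 rose by 2.48 (SE 0.35, adjusted p = 0.00391, edgeR), more than any rise named here. The unnamed gene_01702, gene_01705 and gene_01706 fell by 1.53, 1.58 and 1.53. bceA_1 and yxdM_1, which adjoin each other, are named for transporters of peptide antibiotics. They stood at 59.8 and 346 CPM in Lcr35 alone replicate 3, against 22.1 to 23.4 and 121 to 122 CPM in the other Lcr35 alone libraries, and without that library their log2 fold changes were -1.47 and -1.33.

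In all, 83 of 2732 genes were called with STS, 54 higher and 29 lower, and 27 and 18 of them changed at least 2-fold. The 3 values of each group lay apart for all 83, and for 25.1% of all genes tested, where chance gives 10%. The count fell without each library of this comparison: it was 55, 51 and 34 without Lcr35 alone replicate 1, 2 and 3, and 27, 33 and 35 without Lcr35 + STS replicate 1, 2 and 3. Leaving out a library also lowers the power of the test, so a call lost in this way need not rest on that library. Scaled by library totals alone, which lowered the median log2 fold change of all genes by 0.16, 29 genes were called higher and 34 lower, and with only the 6 samples fitted the split was 76 and 24. DESeq2 called 155 (101 higher and 54 lower), the replicate block 103 (72 and 31), and the block in only the 6 samples, chosen after seeing the data, 185 (131 and 54). Of the 20 genes with a symbol and the largest changes, 11 kept their call in every alternative run for single genes, which left out the other filters. The other 9 (nanT, hrcA, hisC_1, psaA, bceA_1, yxdM_1, mepH_2, dltC and czrA_2) missed the threshold without Lcr35 + STS replicate 2 (adjusted p 0.0538 to 0.142), and all of them except dltC did so without replicate 1 (0.0864 to 0.190). nanT, hrcA, yxdM_1, mepH_2 and czrA_2 also missed it without Lcr35 + STS replicate 3 (0.0507 to 0.221), and nanT, hrcA, hisC_1, psaA, mepH_2 and czrA_2 without Lcr35 alone replicate 3 (0.0697 to 0.131). Further calls ended without Lcr35 alone replicate 1 (hrcA, psaA and czrA_2, 0.0677 to 0.124), Lcr35 alone replicate 2 (nanT and czrA_2, 0.0653 to 0.112), Lcr35 + Candida replicate 2 (mepH_2, 0.0617) and Lcr35 + Candida replicate 3 (hrcA and mepH_2, 0.0509 to 0.0656). With only the 6 samples hrcA, hisC_1, yxdM_1 and mepH_2 missed the threshold (0.0516 to 0.0869), and by library totals hrcA and psaA did (0.0509 to 0.0736). nanT and czrA_2 missed it with limma (0.0709 to 0.127) and with counts thinned to the smallest size factor (0.106 to 0.114), and czrA_2 with the replicate block (0.0564).

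**Figure D2:**
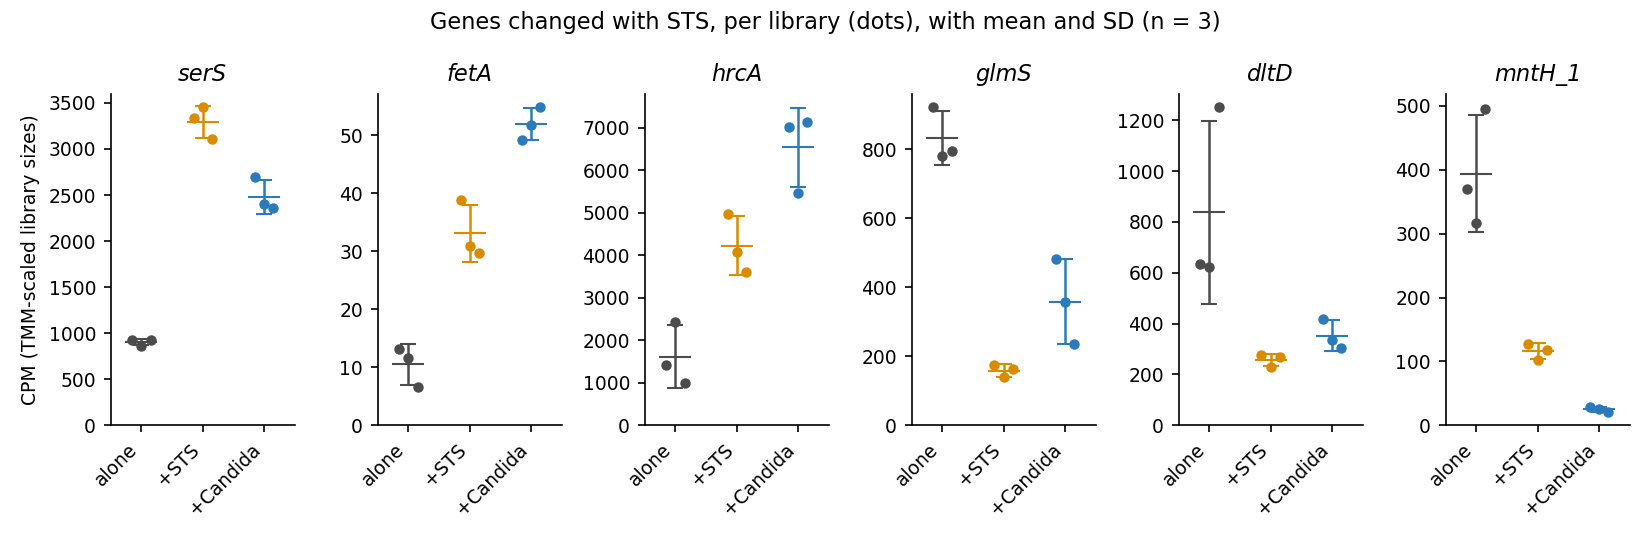
Expression (y axis, CPM on TMM-scaled library sizes, a separate scale for each gene) of 6 genes in Lcr35 alone, with STS and with Candida (x axis). Dots are the 3 libraries of a group in replicate order, the horizontal mark is their mean and the bars are ± SD; serS lies at 905 CPM in Lcr35 alone and 3297 with STS, and glmS at 833 and 159.

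Among the lists of genes fixed beforehand, those of sulfur metabolism held no gene called with STS by edgeR in all 9 samples. The lists could hold only genes with a symbol, which 1150 of the 2781 genes lack. Of the 83 genes called with STS, 63 carried a symbol, so sulfur genes without one would be missed. Sulfur genes under symbols other than those listed would be missed too. For example, yecS_2, named for amino acid uptake and called higher with STS, was in no sulfur list, and its substrate was not examined. In the list of sulfur amino acid metabolism and uptake, 0 of 15 members were called, and camera gave an adjusted p of 0.365. The members with the smallest adjusted p were the cysteine synthesis genes cysE (log2 fold change 0.46, SE 0.17, adjusted p = 0.229) and cysK (0.33, SE 0.17, adjusted p = 0.456). In the list of sulfur transfer and iron-sulfur assembly, 0 of 7 members were called, and camera gave 0.232; iscS_1 stood at 0.43 and thiI at 0.41. At an unadjusted p under 0.05 there were 1 and 2 members in these lists, and DESeq2 and limma also called 0. With the replicate block in only the 6 samples of the comparison, an alternative chosen after seeing the data, 1 and 2 members were called higher: cysE (adjusted p = 0.0420, range over its alternatives 0.0420 to 0.640), iscS_1 (0.0351, range 0.0351 to 0.645) and thiI (0.0417, range 0.0417 to 0.699). In data simulated without pairing, 20.9% of genes changed 1.5-fold were recovered for STS.

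Heat shock and protein quality control genes were higher with STS: 8 of 17 members rose (11 adjusted over the list alone), the median log2 fold change was 0.84, and camera gave an adjusted p of 1.09e-11 (adjusted p = 0.251 with an estimated correlation). The examples were hrcA (1.39, SE 0.29), which encodes the heat shock repressor, the chaperone gene dnaJ (1.02, SE 0.22), ctsR (0.88, SE 0.19) and clpC_1 (0.85, SE 0.17). Expression of the list varied among the controls, with a mean log2 CPM of 10.6, 10.8 and 10.1 in Lcr35 alone replicates 1, 2 and 3 against 11.1 to 11.3 with STS. Of its 17 members, 0 were called without Lcr35 alone replicate 3 or without any of the 3 STS libraries, 2 without Lcr35 alone replicate 1 or Lcr35 + Candida replicate 3, 6 without Lcr35 alone replicate 2, and 0 when scaled by library totals. camera passed in each of these.

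Arginine and amine metabolism (2 of 4 rose, 3 adjusted over the list alone; camera adjusted p = 0.000218, adjusted p = 0.139 with an estimated correlation) rested on argG (1.15, SE 0.20) and argH (from 81.0 ± 11.8 to 174 ± 24.0 CPM), the enzymes of the last steps of arginine synthesis. The call of argG was lost without Lcr35 alone replicate 3 or Lcr35 + STS replicate 1 (adjusted p 0.0558 and 0.0812). Thiol redox and oxidative stress (camera adjusted p = 0.0243, adjusted p = 0.293 with an estimated correlation) had 1 called member of 17 (2 adjusted over the list alone), the peroxide regulator gene perR, which rose by 0.92 (SE 0.20), while trxA_1 stood at 0.65 (adjusted p = 0.0652). That list missed the threshold without Lcr35 + STS replicate 2 (0.0541), and perR did so without any of the 3 STS libraries, Lcr35 alone replicate 2 or 3 or Lcr35 + Candida replicate 3 (up to 0.163), and by library totals (0.0509).

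Other lists passed with hardly any called member. Aminoacyl-tRNA synthetases had 1 of 21, serS (camera adjusted p = 0.0243), and ribosomal proteins had 1 of 50, rplL (0.65, camera 0.0363); both medians (0.10 and 0.12) turned negative when scaled by library totals. Lactose, galactose and tagatose use had 0 of 25 (2 adjusted over the list alone; camera 0.0393, or 0.0716 with the replicate block), with lacD_1 at 1.00 (adjusted p = 0.0603). DESeq2 called 3 of its members, the replicate block in only the 6 samples 5, and a further 3 alternatives 1 or 2; its median of 0.16 was -0.01 when scaled by library totals. Purine synthesis was lower, with 1 of 17, purH (-0.60; 2 adjusted over the list alone; camera 0.0286). For these 4 lists the adjusted p with an estimated correlation was 0.739. The synthetases missed the threshold without Lcr35 alone replicate 1 (0.0654), Lcr35 alone replicate 2 (0.209) or Lcr35 + STS replicate 3 (0.197). The ribosomal list missed it without Lcr35 alone replicate 1 (0.0581), replicate 2 (0.142), Lcr35 + STS replicate 2 (0.115) or replicate 3 (0.205). The lactose list missed it without Lcr35 alone replicate 1 (0.246), Lcr35 + STS replicate 2 (0.115) or replicate 3 (0.0676), and the purine list without Lcr35 alone replicate 1 (0.0654), replicate 3 (0.239) or Lcr35 + STS replicate 2 (0.194). The call of rplL was lost without any of the 6 libraries of this comparison or Lcr35 + Candida replicate 3 (adjusted p 0.0535 to 0.188), and by library totals (0.173). That of purH was lost without Lcr35 alone replicate 1 or 3, each STS library or Lcr35 + Candida replicate 3 (0.0597 to 0.190), with only the 6 samples (0.0630) and with limma (0.0518).

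Cell wall synthesis and D-alanylation was lower by camera (adjusted p = 0.0243, adjusted p = 0.739 with an estimated correlation, and 0.132 without Lcr35 + STS replicate 2), with 4 of 24 members fallen: glmS, dltA, dltD and dltC. Its mean log2 fold change was -0.27 but its median 0.06, which turned to -0.10 when scaled by library totals. Metal ion transport went both ways (2 of 10 rose, znuC and znuB, and mntH_1 fell; camera adjusted p = 0.357). The lists of ATP synthase, glycolysis, pyruvate metabolism, phosphotransferase systems, pyrimidine synthesis, fatty acid synthesis, exopolysaccharides and pili, peptide uptake and glycerol metabolism held 0 members called by edgeR in all 9 samples and did not pass. At an unadjusted p under 0.05 they held 1 pyruvate, 2 phosphotransferase and 1 pyrimidine gene, DESeq2 called 1 pyruvate gene, and limma called 0. The exopolysaccharide gene rmlB was called lower without Lcr35 alone replicate 1 (adjusted p = 0.0463, range over its alternatives 0.0463 to 0.895), and the replicate block in only the 6 samples called 2 phosphotransferase genes. 8 of 20 lists passed with STS with the preset correlation, 6 higher and 2 lower, and 0 with an estimated correlation, where 3 had an unadjusted p under 0.05. fry passed 3.

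The comparison of Lcr35 with Candida against Lcr35 alone asks how the bacterium's transcripts differ after 6 h with the yeast, in cultures that also held the yeast's Sabouraud medium. Among the 10 largest rises, bglF_2 (gene_00698), named for a beta-glucoside phosphotransferase transporter, rose from 36.7 ± 7.18 to 7684 ± 1325 CPM (log2 fold change 7.71, SE 0.28, adjusted p = 7.92e-09). Next to it lie treA (gene_00699), the enzyme that splits trehalose phosphate, and its regulator gene treR (gene_00700), which rose by 7.51 (SE 0.33) and 6.95 (SE 0.41). The myo-inositol catabolism genes iolA (7.64, SE 0.52), iolT_1 (6.91), iolB (6.82) and iolC (6.26) were also among them, as were the mannose-type transporter gene manZ_1 (6.48), the ribose transporter gene rbsC (6.42) and bacC_2 (6.26).

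Among the 10 largest falls by fitted fold change, crcB_2 and cysL_1 had 0 counts in the 3 co-culture libraries. They were at least 14.0-fold and 7.95-fold lower (3.80 and 2.99 on the log2 scale), against a floor of 3 counts over the group. Their fitted values are not bounds, so their rank among the falls is uncertain. bcrR_3 had 1 count in co-culture against 440 in Lcr35 alone, a ratio of 77.2 with a 95% counting interval of 13.8 to 3055. mscL, the gene of a mechanosensitive channel, fell by 4.45 (SE 0.38) on the log2 scale. The fold changes of ubiE (-4.30, SE 0.35), the purine synthesis genes purE (-4.18, SE 0.24) and purK_2 (-3.97, SE 0.21), hemH (-4.04), mntH_1 (-3.96) and bceA_1 (-3.95) followed. In all, 10 genes had 0 counts in the 3 co-culture libraries, 0 of them in a list.

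In total 2198 of 2732 genes were called in co-culture, 1019 higher and 1179 lower, and 782 and 935 of them changed at least 2-fold; the values of the groups lay apart for 80.7% of all genes, where chance gives 10%. The split depended on the scaling. The scaling factors of the co-culture libraries (TMM 0.398 to 0.482 against 1.53 to 1.68 in Lcr35 alone) differed strongly from those of the controls. Scaled by library totals alone, 385 genes were called higher and 2059 lower, and the median log2 fold change moved from -0.16 to -2.03. The changes below are thus relative to the bulk of Lcr35 genes. The count for library totals is given beside each list that passed, and only in part for the other lists.

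Sugar phosphotransferase systems rose broadly in co-culture: 53 of 62 members rose and 4 fell (median log2 fold change 3.06; camera adjusted p = 1.09e-13, adjusted p = 0.607 with an estimated correlation), and 40 of the 53 remained called higher when scaled by library totals, where 14 were called lower and the median was 1.16. Examples were gatC_4 (5.37, SE 0.20), levE_1 (5.74, SE 0.23) and mtlF (4.99, SE 0.21). In the list of lactose, galactose and tagatose use 18 of 25 rose and 4 fell (camera adjusted p = 0.000387, adjusted p = 0.678 with an estimated correlation), 13 of the 18 also by library totals (10 of 25 fell there), with lacD_1 at 6.00 (SE 0.31), lacB at 5.46 (SE 0.29) and lacC_3 at 4.94 (SE 0.26). Of the glycerol metabolism genes 9 of 10 rose (10 adjusted over the list alone; camera adjusted p = 0.000536, adjusted p = 0.607 with an estimated correlation), 4 of these also by library totals, where 2 fell. They include glpK_2 (4.92, SE 0.29), glpO (2.76, SE 0.18), glpF (2.83, SE 0.20) and dhaL (2.33, SE 0.16).

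Pyruvate, acetate and citrate metabolism rose in 13 of 17 members and fell in 3 (median 1.57, which turned to -0.32 by library totals; camera adjusted p = 0.000237, adjusted p = 0.625 with an estimated correlation), and 7 of the 13 remained higher by library totals, where 7 of 17 fell. The pyruvate formate-lyase gene pflB rose from 440 ± 76.2 to 12708 ± 2127 CPM (log2 fold change 4.85, SE 0.22), and the pyruvate dehydrogenase genes pdhD, pdhB and pdhA rose by 4.77, 4.53 and 3.80. Heat shock and protein quality control genes rose in 14 of 17 members and fell in 1 (median 1.48, which turned to -0.38 by library totals; camera adjusted p = 0.00756, adjusted p = 0.678 with an estimated correlation). By library totals 7 of 17 fell. The 4 members still higher there were those with the largest rises, clpC_2 (4.28, SE 0.31), dnaJ (2.88, SE 0.23), clpE (2.84, SE 0.27) and dnaK (2.63, SE 0.27).

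Purine synthesis fell in 16 of 17 members in co-culture (median -2.41; camera adjusted p = 1.52e-05, adjusted p = 0.625 with an estimated correlation) and in all 17 by library totals, with xpt at -3.53 (SE 0.17) and purH at -2.66 (SE 0.15). Cell wall synthesis and D-alanylation fell in 18 of 24 members and rose in 1 (median -1.21; camera adjusted p = 0.00466, adjusted p = 0.625 with an estimated correlation), and all 24 were lower by library totals. mraY (-3.17, SE 0.16), murG (-2.94, SE 0.18), uppP (-2.78, SE 0.17) and murD (-2.75, SE 0.18), genes of peptidoglycan precursor synthesis, were lowest in adjusted p. Fatty acid synthesis fell in 10 of 11 members and rose in 1, with acpP_2 at -3.13, but missed the threshold as a list (camera adjusted p = 0.0919).

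The other lists did not pass camera in co-culture, and most of them went both ways. Of the sulfur amino acid genes 8 of 15 rose and 4 fell (camera adjusted p = 0.677), with cysK at 1.76 and metQ_2 at 1.40, which became -0.11 and -0.48 by library totals. In the sulfur transfer list 2 of 7 rose and 3 fell (0.672), with sufT at -2.19 and iscS_1 at -1.83. In the thiol redox list 6 of 17 rose and 5 fell (0.874), with trxA_1 at 2.45 and nox_2 at -2.60. Ribosomal proteins rose in 26 of 50 members and fell in 8 (0.323), but 2 rose and 43 fell by library totals. Aminoacyl-tRNA synthetases rose in 8 of 21 and fell in 10 (0.933), and glycolysis genes rose in 10 of 19 and fell in 6 (0.777, fbaA_3 4.57, pfkA -3.41). ATP synthase genes rose in 2 of 8 and fell in 4 (0.874), but 0 rose and all 8 fell by library totals. Peptide uptake genes rose in 13 of 28 and fell in 9 (0.777), metal ion transport genes rose in 2 of 10 and fell in 5 (0.543), and exopolysaccharide and pilus genes rose in 1 of 6 and fell in 5 (0.683). Pyrimidine synthesis genes rose in 2 of 10 (1 adjusted over the list alone) and fell in 2 (0.933), and 1 of 4 arginine and amine genes, argR_1, rose (0.777) but stood at -0.15 by library totals. Scaled by library totals, at most 2 members of each of these lists and of fatty acid synthesis were called higher, except for 6 glycolysis genes. Median, mean and test differed in sign for the thiol redox, pyrimidine and peptide lists. nagB rose by 1.92, but stood at 0.04 by library totals. 7 of 20 lists passed with the preset correlation, 5 higher and 2 lower, 0 with an estimated correlation (1 with an unadjusted p under 0.05), and 14 with fry. Beside those 7, fry passed the sulfur amino acid, glycolysis and arginine lists as higher (adjusted p 0.00660, 0.0313 and 0.0209). It passed the sulfur transfer, metal ion, fatty acid and exopolysaccharide lists as lower (0.00222, 0.00227, 0.00272 and 0.0360). As 2198 of 2732 genes were called, most lists were likely to pass fry, and its directions hold for TMM scaling only.

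**Figure D3:**
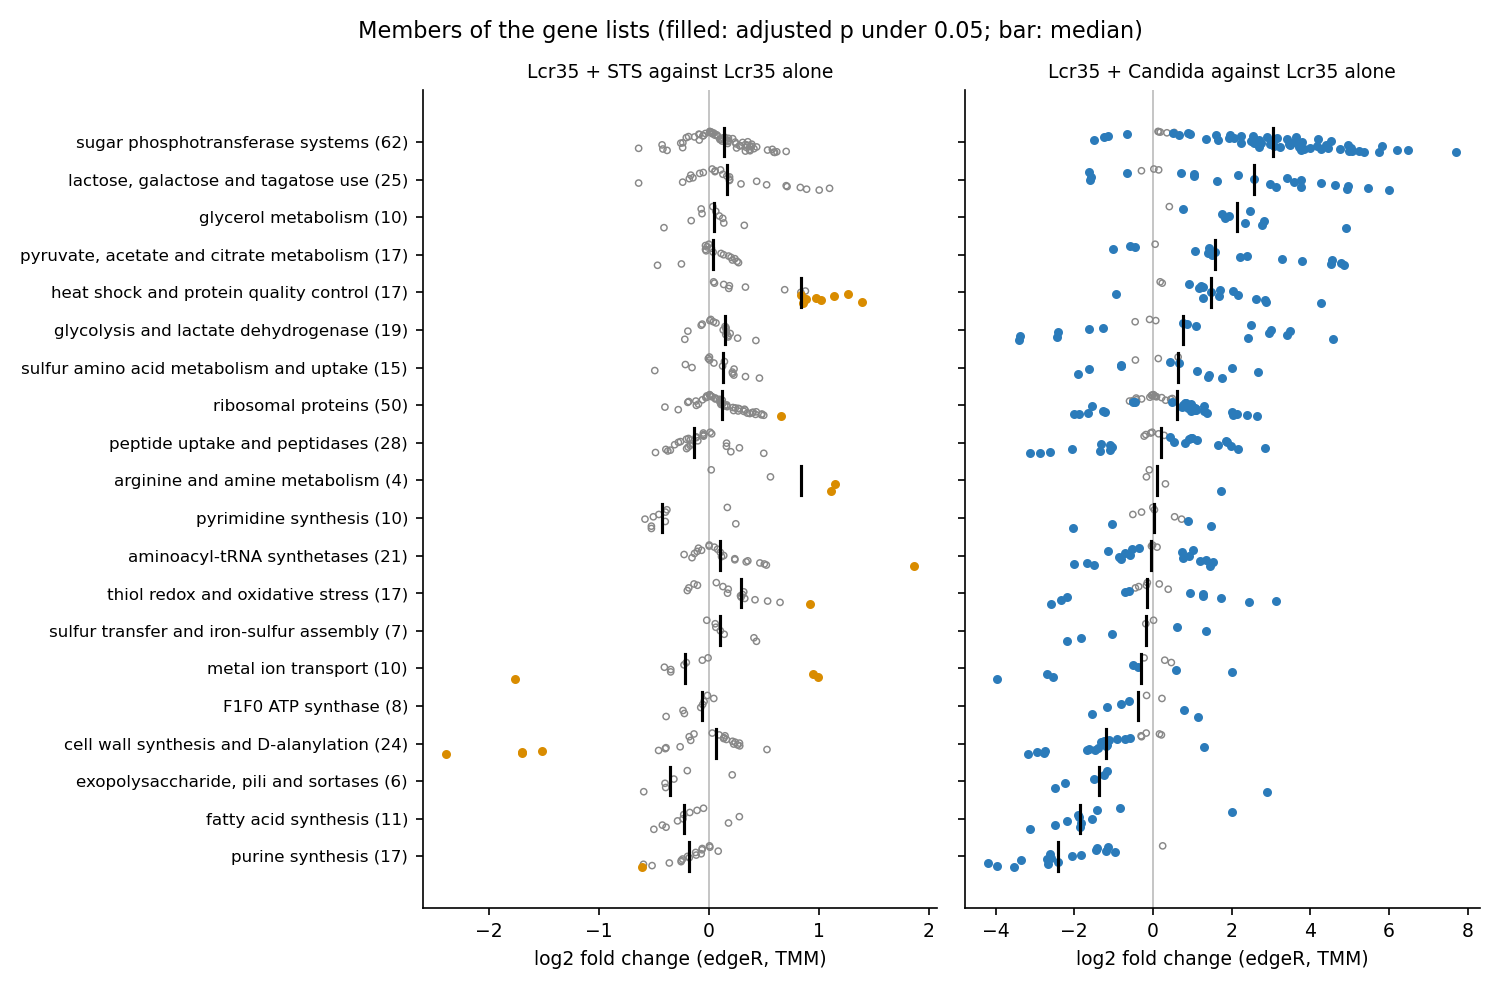
Log2 fold changes (x axis, with a different range in each panel) of the members of 20 gene lists (y axis, number of tested members in brackets) for STS and for Candida against Lcr35 alone. Filled dots have an adjusted p under 0.05, open dots do not, and black bars are medians; 53 of 62 phosphotransferase genes rose with Candida and 0 of 62 with STS, and Candida values shift downwards by 1.87 when scaled by library totals.

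The effects of STS and of Candida were compared in the contrast of the treated groups, in which the controls cancel. 2173 of 2732 genes differed between co-culture and STS cultures, 1007 higher and 1166 lower in co-culture (374 and 2022 when scaled by library totals). Of the 54 genes that rose with STS, 36 also rose and 9 fell in co-culture, and of the 29 that fell, 23 also fell and 2 rose. Independent lists of these sizes would share 20.1 rising and 12.5 falling genes. Unchanged groups simulated against the same controls shared 0, but as they gave at most 1 call for STS and 0 for Candida, this count sets no expectation. The controls were too few to be split, so part of the excess over independent lists may come from the controls that both comparisons share, and by library totals 6 genes rose and 32 fell in both. Across genes, which are not independent replicates, the log2 fold changes correlated with r = 0.38 and a covariance of 0.308, against 0.464 and 0.0358 in the simulation, a difference in covariance of 0.272. The simulated libraries were drawn independently, without the pairing by replicate number, so the values expected from shared controls in paired samples are not known.

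Of the 54 genes that rose with STS, 23 were higher in co-culture than with STS, 20 were lower and 11 did not pass the test of the difference. hrcA was among those that did not pass (difference 0.63, SE 0.29, adjusted p = 0.0630), and its rise of 2.02 in co-culture was 0.14 by library totals (adjusted p = 0.647). serS rose less in co-culture than with STS (difference -0.41, adjusted p = 0.0205), and its rise of 1.46 in co-culture turned to -0.42 by library totals. mntH_1 fell with both, with a difference of -2.19 between co-culture and STS (SE 0.20). The arsenic-type repressor gene arsR_2, among the 10 largest falls between the treated groups (-3.88), rose with STS (1.23) and fell in co-culture (-2.66). nanT also rose with STS (1.70) and fell in co-culture (-1.46). Between the treated groups 6 of 20 lists passed: the phosphotransferase, pyruvate, lactose and glycerol lists were higher in co-culture (adjusted p 7.84e-14, 0.000104, 0.000587 and 0.000313) and the purine and cell wall lists were lower (5.04e-05 and 0.0200). With an estimated correlation the adjusted p of these 6 was 0.635 to 0.751, and 0 lists passed, while fry passed 12. With the replicate block, fatty acid synthesis also passed as lower (adjusted p = 0.0390).

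**Figure D4:**
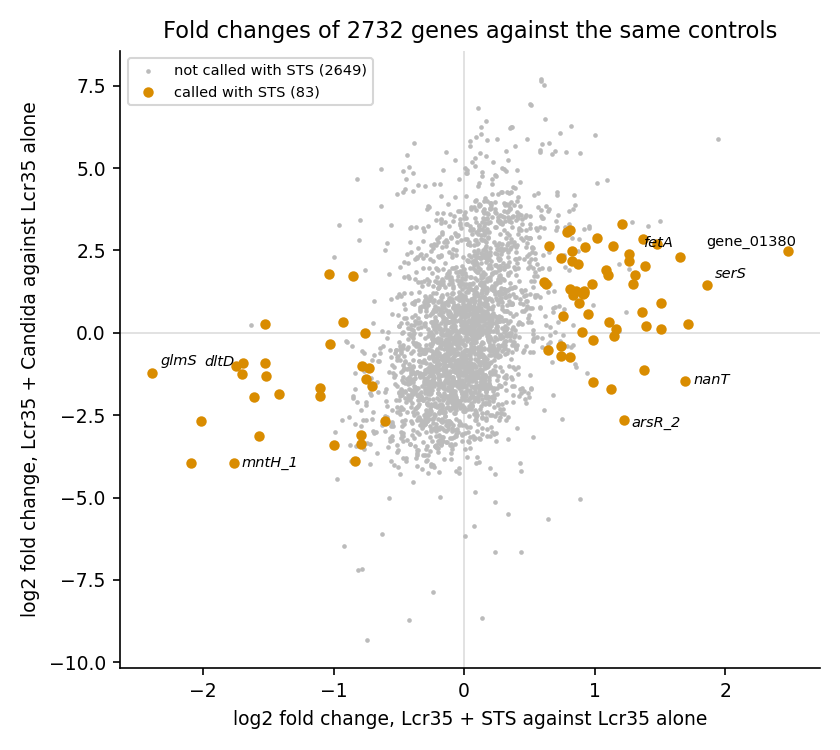
Log2 fold change of each of 2732 genes with STS (x axis) and with Candida (y axis), both against Lcr35 alone. The 83 genes called with STS are filled in orange and all others are grey; 36 of them rose and 23 fell in both comparisons. The lowest points include 10 genes with 0 counts in co-culture, whose fitted values are not bounds.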

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

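The alternatives that scale by library totals alone, thin counts to the smallest size factor, fit the replicate block within 6 samples or match symbols more widely were chosen after seeing the data. The others were fixed before the data were examined.

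The count of genes called with STS (83) was 155 with DESeq2 and 185 with the replicate block in only the 6 samples of the comparison. Leaving out a library gave 27 to 97, of which 27 to 81 were shared with the 83. The other alternatives gave 63 to 103. The counts for Candida (2198) and for Candida against STS (2173) stayed within 1.5 times in every alternative run, at 2105 to 2172 and 2033 to 2178 with a library left out.

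For the overlap of both comparisons against Lcr35 alone, DESeq2 gave 72 genes higher in both, 41 lower in both and 20 in opposite directions, against 36, 23 and 11. Library totals gave 6 higher in both and 17 opposite. Leaving out a library gave 10 to 45 higher in both, 8 to 24 lower in both and 3 to 13 opposite. More STS calls or fewer move these counts by construction.

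Of the list tests, 8 passed for STS, 7 for Candida and 6 for Candida against STS. With an estimated correlation 0, 0 and 0 passed, and with fry 3, 14 and 12. Without a library, 3 to 9 passed for STS, while all 7 and all 6 kept their call for the others. With camera, every list call thus depended on the preset correlation between genes. fry, which uses none and does not compare a list with other genes, passed 3 of the 8, all 7 and all 6 among its own. With 2198 and 2173 of 2732 genes called for Candida and for Candida against STS, most lists were likely to pass fry. Its passes there therefore do not back the camera calls, and fry was not run with library totals.

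Among 30 called genes that the rule gave for STS, 14 kept their call under all 20 alternatives for single genes and 16 lost it under at least 1, and 0 changed sign. For Candida 64 of 71 kept it, 1 lost it and 6 changed sign, and for Candida against STS 62 of 71 kept it, 3 lost it and 6 changed sign. Every change of sign came from library totals, which shift all co-culture values by -1.87 in the median (-1.71 against STS). For Candida, cysK stood at -0.11, metQ_2 at -0.48, serS at -0.42, atpC at -0.72, pyrH at -0.42 and argR_1 at -0.15. For Candida against STS, cysK stood at -0.29, metQ_2 at -0.54, atpC at -0.54, pyrH at -0.50, nagB at -0.88 and argR_1 at -0.54. RLE and upper-quartile scaling shifted the co-culture median by 0.12 and -0.15.

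With the replicate block 103 genes were called for STS (80 of the 83 among them) and 2198 for Candida against STS. Besides czrA_2, the lactose list for STS and fatty acid synthesis for Candida against STS, it changed no other call of a named gene or list in these comparisons. Deviations of same-numbered Lcr35 alone and co-culture libraries correlated with r = 0.02, -0.20 and 0.14, so those samples share only a number. A replicate block for Candida against Lcr35 alone gave 2229 calls and 8 lists, with fatty acid synthesis at an adjusted p of 0.0215, and not every library correlated best with its own number.

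Depth limits genes with few counts in co-culture, where the median count per gene was 326 to 486. With counts thinned to the smallest size factor, 2122 genes were called for Candida and 80 for STS.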

Other observations

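The tests of the most abundant gene, of Candida reads, of neighbouring genes and of groups of genes that share a symbol prefix, and the scaling by library totals, were chosen only after the results were seen, as were the genes outside the rule that are named with them.

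Genes that share the first letters of a symbol often belong to a pathway, and camera was run on 97 such prefixes outside the rule for named genes. In co-culture, groups outside the fixed lists that rose were ribose uptake and use (rbs, 5 of 6 rose, median log2 fold change 5.85, adjusted p = 5.58e-05), inositol catabolism (iol, 11 of 14 rose and 2 fell, 4.04, 0.00331), the kdg genes (6 of 6, 3.65, 5.58e-05), sorbose or sorbitol use (sor, 8 of 9, 3.15, 0.00952) and glycogen metabolism (glg, 5 of 5, 2.60, 0.00553). Scaled by library totals, their medians were 3.97, 2.12, 1.74, 1.27 and 0.71. With STS the glg genes (3 of 5 rose, median 0.79) and the mhq genes, named for quinone resistance (3 of 4 rose, 0.79), had the smallest adjusted p of 1.37e-05 each, and their medians were 0.63 each by library totals. With an estimated correlation 0 of the 97 passed in either comparison (adjusted p 0.708 for the co-culture groups named, 0.554 for mhq and 0.607 for glg with STS).

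The genes with the 3 identifiers before gene_00632, which are ywrO, AADAC and mutY, rose in co-culture by 4.25, 4.29 and 3.90 on the log2 scale, close to its 3.67. Of the 83 genes called with STS, 52 had a neighbouring identifier called in the same direction, against a mean of 2.67 and at most 15 in 10000 random draws (permutation p = 0.0001, the smallest these draws can give). This is consistent with co-transcription in operons, which identifiers alone do not show. The densest window of 20 identifiers, from gene_01692, held 9 calls, 3 higher and 6 lower, against at most 7 in random draws (permutation p = 0.0001, the smallest possible). It includes psaA, czrA_2, ctpF and mntH_1, named for metal transport or its control, and its other called genes carry no symbol. The draws place calls singly, without the runs of neighbours above, so the window is not separate evidence of a cluster.

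The co-culture libraries held 49.9% to 56.3% of their counts in the 10 most abundant genes of each library, against 19.4% to 25.6% in Lcr35 alone. A single gene is not the whole cause: with gene_00632 left out, the next 9 genes of each library took 35.1% to 37.1% of the remaining counts, against 14.9% to 18.0% in Lcr35 alone. Reads of C. albicans assigned to these genes stay open, since foreign reads may match a few genes only and no sequences were at hand. Conserved ATP synthase and ribosomal protein genes had a median log2 fold change of 0.47 (quartiles -0.42 to 1.02) against 2.46 for the 10 genes with the highest mean share over all libraries, which co-culture values helped to choose. Stress, later growth phase and partial RNA loss in co-culture remain untested.

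The rise of phosphotransferase genes in co-culture was tested against scaling and depth. By library totals 40 of the 53 members remained called higher and 14 of 62 were called lower, so scaling is not the whole cause for those 40 but decided the calls of the others. With counts thinned to the smallest size factor 50 remained called higher, which argues against fewer counts per gene as the whole cause. The list was also higher in co-culture than in STS cultures, by a median of 2.85. As every co-culture also held Sabouraud medium, the yeast and the carried-over medium, or a changed sugar supply, cannot be told apart.

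For heat shock genes with STS, the calls without the replicate block were mostly lost when single libraries were left out, which also lowers power. Without Lcr35 alone replicate 3 the median fell from 0.84 to 0.63 and 0 of 17 members were called. The median was 0.92 and 0.94 without Lcr35 alone replicate 1 or 2. Without each STS library it stayed at 0.81 to 0.83, though 0 members were called there too. The replicate block called 9 members, or 10 in only the 6 samples. In pairs of the same replicate number, taken after these values were seen, the list's mean log2 CPM was higher with STS by 0.67, 0.45 and 1.05. Lcr35 alone replicate 3 stood at -0.40 in the list's mean log2 CPM relative to the mean of its group, and so raised the estimated median. Why that library stood low stays open. Scaled by library totals the median was 0.69 and the calls went from 8 to 0: hrcA moved from 1.39 (SE 0.29, adjusted p = 0.0314) to 1.23 (SE 0.28, 0.0509), a shift of about that of all genes (-0.16). Scaling is therefore unlikely to be the whole cause, though it decided the calls. An effect of STS stays open and untested beyond this comparison.

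Splits of the 6 samples of a comparison into 3 and 3 number 10, too few for a share under 0.1. For STS the real split called 100 genes and the highest other 0, and for Candida and for Candida against STS it called 2130 and 2156 against 0; in each, 1 of 10 splits called as many. Of the other splits for STS and for Candida against STS, 3 part all 3 pairs of the replicate numbers as the real split does, and 6 part 1 pair. Each of the other splits mixes the groups, which puts part of their difference into the spread within each side. Few calls were therefore to be expected in them, and these counts of genes do not test chance. In the list tests the real split passed 9 lists for STS (highest other 7, 1 of 10 as many), 7 for Candida (highest other 10, 7 of 10 as many) and 6 for Candida against STS (highest other 9, 7 of 10 as many).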
